A study of Capra hircus with 4 samples.

How the data were processed

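Single-cell RNA sequencing was performed on dissociated pancreas from 4 female Liuyang black goats, 2 sampled at 10 days of age, before rumination, and 2 at 6 months of age, after its onset. Per the labels' protocols, minced tissue was digested with collagenase, dispase and DNase, filtered, freed of red blood cells and dead cells, and loaded on the 10x Genomics platform with 3' version 3 chemistry for a capture target of 8000 cells. The deposited values are whole UMI counts per gene and barcode, held in a single matrix that aggregates 4 libraries and lists 27137 genes and 27179520 barcodes, with 73143416 entries and 247275915 UMIs. The matrix is unfiltered: each library lists 6794880 barcodes. The submitters' processing notes name Cell Ranger 3.1.0 and Seurat 3.1.1, whereas the matrix was written by Cell Ranger 5.0.1, per the file headers. The genome build, the annotation and any thinning of libraries to equal depth during aggregation are not given in the sources used here.

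Barcodes carry a library number from 1 to 4, and no label ties a number to an animal or an age. The libraries were therefore left unassigned, no age was given to any of them, and the planned edgeR comparison of the ages was not run. Every comparison set classes of cells against each other inside each library. Values are given per library or as the median and range over libraries, with no test and no p-value, because the libraries are not replicates of a known group.

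Gene names are the symbols paired with numeric gene IDs in the deposited feature list. Of its 27137 IDs, 27103 matched the RefSeq gene table of assembly ARS1.2, which was used for names and for the order of neighbouring genes and not for coordinates. Symbols that start with LOC, which carry no gene name, make up 10744 of the list, and 6 symbols stand on more than 1 row and were kept apart by ID. Mitochondrially encoded genes were not analysed here (0 IDs matched the mitochondrial chromosome), so the planned limit of 20% mitochondrial UMIs removed nothing and its 10% alternative was not run.

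A barcode was called a cell when its UMI count exceeded 1/10 of the 99th percentile among the 8000 top barcodes of its library and it held at least 500 genes. Doublets were scored per library with Scrublet in scanpy 1.11.5 and removed at the automatic threshold. That threshold marked 77 of 2890 barcodes in library 1, 2 of 3326 in library 2, 111 of 4107 in library 3 and 4 of 3087 in library 4. Almost none were thus removed in libraries 2 and 4, and how many doublets remained was not estimated. An alternative that removed the 5% of cells with the highest scores in each library was added after seeing this. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 with igraph 0.11.9. Libraries were clustered jointly with no batch correction. The genes of 20 functional lists were left out of the clustering, so that they could be compared between clusters.

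Markers in 23 sets were fixed before the data were examined, and of their 182 genes 163 were matched by symbol. Clusters were named from these sets, except those for pancreatic polypeptide cells, epsilon cells and the cycling state, which gave no names. A class name required at least 3 markers raised 2-fold over the mean of the other clusters and seen in at least 10% of cells. These thresholds, and the rule that left a cluster unnamed when it carried over 0.5 of the matched markers of another lineage or was led by at least 3 cycling genes, were set after seeing the data. Names ending in "-like" are rebuilt here and can differ from the study's own annotation. The 2 clusters left unnamed held 0.391%, 0.782%, 3.10% and 12.8% of the cells of libraries 1 to 4.

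For each class and library, deposited UMI counts were summed and expressed as counts per 1000000 (CPM). The log2 ratio between classes was taken on the scale log2(CPM + 1), which understates the difference of genes with low counts. Of 274 list genes, 228 were matched by symbol, and the others were not used here. By a rule fixed before the data were examined, a list gene was called higher or lower when its log2 ratio reached 1 or -1 in every library in which both classes had at least 20 cells, with at least 20 counts in the higher class in each. The 30 called genes with the highest absolute median log2 ratio are named per comparison. Other genes in the text were chosen after their values were seen. On counts simulated for all 27137 genes at a dispersion of 0.05, with 200 genes changed, the call rule recovered 100% of changes of log2 3 in each comparison. It recovered 61% of changes of log2 1.5 for acinar-like against ductal-like cells and 51% for endocrine-like against exocrine cells. For stellate-like against endothelial-like cells it recovered 43%, and for immune-like against other cells 44%. In each comparison 0 or 1 unchanged gene was called, with 0 calls in the wrong direction. Both classes were simulated from their mean profile, with no shift of all genes, doublets or free RNA added. Wrong calls from those were therefore not measured. The changed genes were drawn only from those with at least 20 expected counts in both classes of each library used. The dispersion was set and not estimated from these libraries, where some ratios spread widely (PIGR, acinar-like against ductal-like, -9.99 to -4.31). The recovery therefore does not carry over to such genes or to genes with fewer counts.

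Counts per class carry exact Poisson 95% intervals and shares of cells exact Clopper-Pearson 95% intervals, which cover counting error only. A share of 0 is given with the limit that 3 cells would set. Free RNA was described from barcodes with 10 to 100 UMIs. Its share in cells was estimated from 12 acinar genes in immune-like and endothelial-like cells. These are the 8 matched acinar markers and the 4 matched lipid digestion genes. They are called acinar enzyme genes here, although some, such as SYCN, GP2, SPINK1 and ERP27, do not encode enzymes. Alternatives changed the UMI and gene minimum, the treatment of doublets, the clustering, free RNA, the pseudocount, the count minimum, the averaging over cells and the libraries included. Alternatives that centred ratios on the median of all genes, or left LOC108634769 out of the totals, were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and anndata 0.12.19, and plots matplotlib 3.10.9.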

Results

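The goat pancreas was profiled cell by cell at an age before rumination (10 days, 2 animals) and an age after its onset (6 months, 2 animals), to describe the cell types of a ruminant pancreas. The 4 libraries held 43297855, 82817057, 65937591 and 55223412 UMIs in the order of their numbers. Cell calling left 2813, 3324, 3996 and 3083 cells, 13216 in all, with median depths of 6174, 8935, 7960.5 and 8185 UMIs and 2046, 2386.5, 2380 and 2521 genes per cell. Called cells held 62.7%, 59.4%, 67.8% and 59.0% of the UMIs of libraries 1 to 4. No label tied a library to an age, so the libraries are reported by number.

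Stellate-like cells were the most numerous class, with 4862 of the 13216 cells. They were named from a joint marker set of stellate cells and fibroblasts, which does not tell the 2 apart. Endocrine-like cells followed with 2953, acinar-like cells, the source of digestive enzymes, with 2520, and immune-like cells with 1210. Ductal-like cells numbered 491, endothelial-like cells 344, pericyte/smooth muscle-like cells 147 and mesothelial-like cells 135. The endocrine-like share ranged from 20.8% to 24.6% with a median of 22.1%, but from 12.1% in library 2 to 25.3% in library 4 with a minimum of 1000 UMIs, and up to 30.3% in library 4 when each library was clustered on its own. The acinar-like share ranged from 2.30% to 37.9% and the immune-like share from 1.02% to 26.4%.

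The acinar-like share was 13.2% (95% interval 12.0% to 14.5%) in library 1, 37.9% (36.2% to 39.5%) in library 2, 20.5% (19.3% to 21.8%) in library 3 and 2.30% (1.80% to 2.90%) in library 4. Immune-like cells made up 9.42% (8.37% to 10.6%), 1.02% (0.709% to 1.43%), 2.45% (2.00% to 2.98%) and 26.4% (24.8% to 28.0%) of libraries 1 to 4. Stellate-like shares were 45.3%, 29.4%, 41.1% and 31.5%, and ductal-like shares 2.13%, 5.14%, 6.23% and 0.357%. When each library was clustered on its own, library 4 had no ductal-like cluster (0%). Endothelial-like shares were 4.80%, 3.13%, 1.13% and 1.95%. Mesothelial-like cells were 0.826% of library 3 and 3.31% of library 4. None were found among 2813 and 3324 cells of libraries 1 and 2 (0%), which allows shares of up to 0.107% and 0.0903%. A minimum of 1000 UMIs, in place of library thresholds between 3403 and 5525, raised the cells called to 9786 in library 2 and 6310 in library 4, and lowered the acinar-like share of library 2 from 37.9% to 15.8%, below the 19.4% of library 3. The immune-like share of library 4 was then 43.1%, so the shares and their order depended on the UMI threshold.

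**Figure D1:**
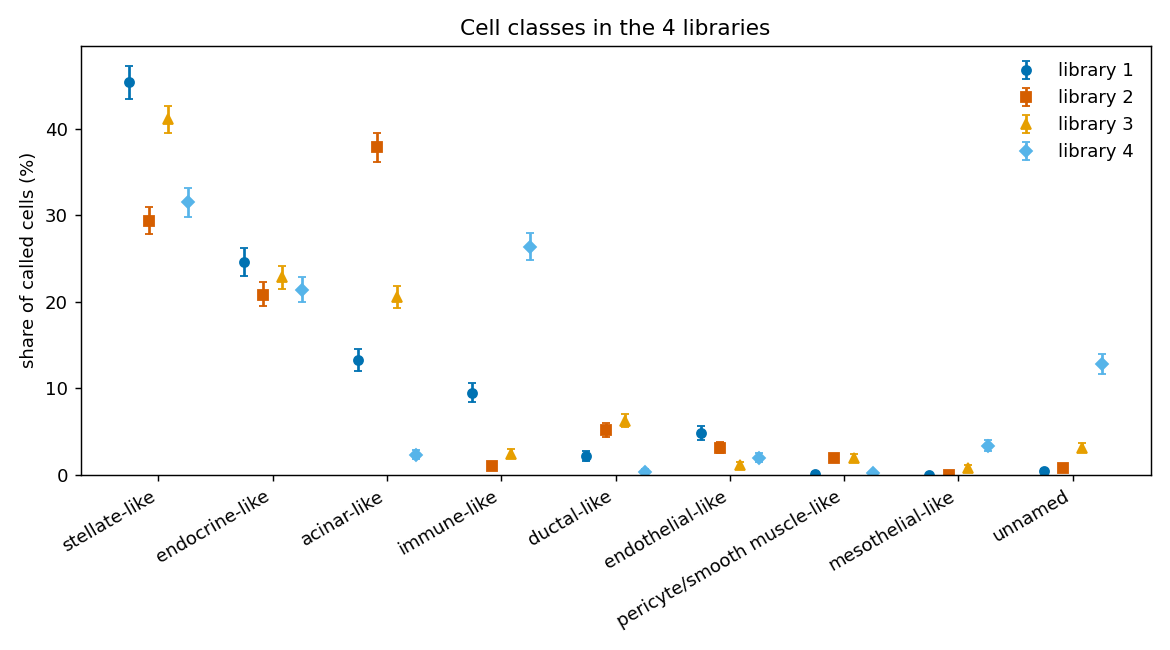
Share of called cells in each class (vertical axis, percent) for libraries 1 to 4, with exact 95% binomial intervals as bars. Acinar-like shares spread from 2.30% to 37.9% at these thresholds, and from 1.11% to 19.4% with a minimum of 1000 UMIs, which is not drawn.

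Within the endocrine-like class, beta-like cells, which make insulin, were 44.7% (40.9% to 48.5%), 61.0% (57.2% to 64.6%), 47.3% (44.0% to 50.6%) and 83.0% (79.9% to 85.8%) of libraries 1 to 4. Alpha-like cells, which make glucagon, were 1.45%, 13.0%, 12.4% and 1.67%, and delta-like cells, which make somatostatin, 10.8%, 3.90%, 9.0% and 2.74%. The remaining 43.1%, 22.1%, 31.3% and 12.6% lay in cluster 4, led by the pancreatic polypeptide gene PPY. Only beta, alpha and delta markers were tried for subtype names, and cluster 4 met too few of them. The fixed marker set of pancreatic polypeptide cells was not tried, so the lack of a name says nothing about that cell type. Cluster 2 held most beta-like cells of libraries 1 and 4 and clusters 22 and 26 those of libraries 2 and 3. An unnamed cluster of 404 cells, 389 of them from library 4, carried endocrine and neutrophil markers together, and another of 150 cells, 123 from library 3, was led by cell division genes over an endocrine background.

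The list genes furthest lower in acinar-like than in ductal-like cells included those of an apolipoprotein and of bicarbonate and chloride transport. APOA1, an apolipoprotein, was lower in acinar-like cells by a median log2 ratio of -8.61 over libraries 1, 2 and 3 (range -11.13 to -7.74), and FABP3, a fatty acid binding protein, by -7.08 (-7.18 to -6.70). The bicarbonate transporter SLC4A4 had a ratio of -5.66 (-6.77 to -4.80), the chloride channel CFTR -4.65 (-6.92 to -4.03) and SCTR, the secretin receptor, -4.08 (-8.49 to -3.78). Acinar-like cells were higher for PDIA2, a pancreatic protein disulfide isomerase, at 1.80 (1.09 to 4.10), and for the water channel AQP8, at 1.80 (1.06 to 3.70). APOA1 reached 16119 CPM (15782 to 16461) in ductal-like cells of library 1, 8245 in library 2 and 9867 in library 3, against 6.18, 20.1 and 45.3 CPM in acinar-like cells.

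Of 199 list genes measured in this comparison, 7 were higher, 48 lower and 144 not called in acinar-like cells. The median log2 ratio of all 6725 genes with enough counts was -1.32. Relative to that shift the split was 39 higher and 12 lower, so single calls near the shift depended on it. The 10 leading genes took 64.4%, 56.7% and 51.8% of acinar-like UMIs in libraries 1 to 3, and 9.46%, 28.0% and 17.4% of ductal-like UMIs. Of the 30 named genes, 14 were also called after centring, among them APOA1 (-7.49), FABP3 (-5.58), SLC4A4 (-4.02), CFTR (-3.53), PIGR, the epithelial immunoglobulin receptor (-3.52), SCTR (-2.96), PDIA2 (2.92) and AQP8 (2.92).

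Among 4 lipid digestion enzymes, 3 were higher in acinar-like cells before and after centring: CEL (1.75), PNLIPRP2 (1.74) and PLA2G1B (1.71). In libraries 2 and 3 the ductal-like sums include 50 and 45 cells with an enzyme share of at least 5%. These cells lower the enzyme ratios there, so the ratios do not describe the typical ductal-like cell. How far they affect other acinar genes was not measured. PNLIP, the main pancreatic lipase, was not called, with a median of 1.31 (0.30 to 4.02). Acinar-like cells of libraries 2 and 3 held only 7 and 26 counts of it (0.229 and 1.48 CPM). The pseudocount therefore bounds the ratios there, and the median is near the floor. The highest ratio came from library 1, where PNLIP stood at 13026 CPM. Of 11 duct fluid and bicarbonate transport genes, 4 were lower, and 3 were lower after centring. Of 25 genes of protein folding in the endoplasmic reticulum, 1 was higher and 2 lower, which became 12 and 0 after centring. The 7 acinar transcription factors gave 0 calls, and 6 higher calls after centring, with centred medians of 3.01 for BHLHA15, 2.72 for PTF1A and 2.45 for RBPJL. Immediate early and dissociation genes gave 11 lower calls among 16, none of which held after centring, where 1 gene, MYC, was higher at 2.38. Of 21 matrix genes, 8 were lower, and 2 after centring, with TIMP1, a metalloproteinase inhibitor, at a centred median of -2.91. Of 16 lipid metabolism genes, 4 were lower, and 2 after centring, APOA1 and FABP3. All 3 oxidative phosphorylation genes were lower, and 0 after centring.

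Clusters behind the acinar-like class differed between libraries: cluster 3 held all such cells of library 1, clusters 23 and 24 most of library 2, and clusters 27 and 18 most of library 3. Ductal-like cells came mainly from cluster 9 in library 1 and from cluster 17 in libraries 2 and 3. In libraries 2 and 3 the 12 acinar enzyme genes took 6.92% and 5.37% of ductal-like UMIs. They took 0.210% and 0.222% in stellate-like cells, and 1.35% and 0.543% in endothelial-like cells. The 50 of 171 and 45 of 249 ductal-like cells with a share of at least 5% carried most of the ductal-like enzyme UMIs. The median per ductal-like cell was 0.535% and 0.508%. Without library 2 the higher count was 17, and library 4, with 11 ductal-like cells, did not enter.

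Endocrine-like cells were set apart from the exocrine cells, acinar-like and ductal-like together, by genes of hormone processing and regulated secretion. PCSK1, the protease that cuts prohormones, was higher by a median log2 ratio of 7.38 over 4 libraries (6.55 to 10.74), and SCGN, a calcium-binding protein of secretory cells, by 7.29 (6.22 to 8.75). The transcription factor NKX2-2 (5.43) was higher, as were ABCC8 (5.58) and KCNJ11 (4.46), the subunits of the ATP-sensitive potassium channel, and the glucose transporter SLC2A2 (5.40). Among the genes lower were ZG16, a zymogen granule protein, at -6.31 (-7.50 to -4.63) and CEL, a lipase of pancreatic juice, at -6.07 (-7.08 to -5.13).

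Of 208 list genes measured, 35 were higher, 27 lower and 146 not called. The median of all genes was 0.98, and relative to it 27 were higher and 36 lower. Each of the 30 named genes was called in the same direction after centring. Of 17 hormone processing and secretion genes, 14 were higher, and 13 after centring. VAMP2, a synaptic vesicle protein, lost its call, with a centred median of 0.72. The transcription factors FOXA1 and FOXA2 lost theirs, with centred medians of 0.88 and 0.69. Of 7 acinar transcription factors, 4 were lower, with RBPJL at -5.10, PTF1A at -3.94 and BHLHA15 at -3.64.

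Amino acid genes went both ways in this comparison. Of 15, the transporters SLC7A8 (4.81) and SLC7A2 (4.33) were higher and 7 were lower, among them GATM, which makes guanidinoacetate for creatine (-5.94), PHGDH, of serine synthesis (-4.66), and the glutamine transporter SLC1A5 (-4.15). Of 11 genes of zymogen granules and secretagogue receptors, 1 was higher, 2 lower and 8 not called. Lipid digestion enzymes were lower in 3 of 4 genes, and the proteases and inhibitors in 2 of 3, CELA1 (-5.26) and SERPINI2 (-5.35). Of 11 fetal and neonatal growth genes, 4 were higher, including the imprinted PEG3 (4.60) and the prolactin receptor PRLR (4.26). APOA1 had a ratio of -7.36, with a range from -9.36 to -3.91. In libraries 1 to 3 ductal-like cells made this contrast, at 16119, 8245 and 9867 CPM. Endocrine-like cells there held 1.91, 40.7 and 22.3 CPM, against 6.18, 20.1 and 45.3 in acinar-like cells, so in library 2 they exceeded acinar-like cells. The exocrine side was made of 432, 1429, 1068 and 82 cells in libraries 1 to 4.

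Named genes higher in stellate-like than in endothelial-like cells included collagens, and those lower included vascular and lymphatic genes. COL6A3, COL6A1 and COL6A2, the chains of collagen VI, were higher by median log2 ratios of 4.90 (3.11 to 8.43), 4.62 (3.43 to 9.22) and 4.34 (3.04 to 6.26). DLK1, an imprinted gene of immature mesenchyme, was higher by 5.03 (3.35 to 8.06), and LOX, which cross-links collagen, by 4.57 (2.16 to 5.34). The lymphatic genes MMRN1 (-9.80, -11.10 to -9.02), LYVE1 (-8.91) and PROX1 (-7.92), and the endothelial transcription factor SOX18 (-8.60), were lower. MMRN1 stood at 2312, 1056, 606 and 2470 CPM in endothelial-like cells of libraries 1 to 4.

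Of 195 list genes measured, 18 were higher, 22 lower and 155 not called. Relative to the median of all genes, -0.25, the split was 21 higher and 20 lower. Each of the 30 named genes kept its call after centring. Of 21 matrix genes, 11 were higher in stellate-like cells, including POSTN (4.05), FBN1 (3.84) and BGN (3.57), and TGFB1, a growth factor, was lower (-3.13). Among the 16 vascular genes, 11 were lower, and 10 after centring. ERG, an endothelial transcription factor, had 278 counts in endothelial-like and 2 in stellate-like cells over the 4 libraries, a ratio of 1573 (95% counting interval 432 to 13060). Of 7 antigen presentation genes, 4 were lower, with CD74, the invariant chain of MHC class II, at -4.91, and CTSH was higher. Of 11 fetal and neonatal growth genes, 4 were higher: DLK1, PEG3 (3.42), CDKN1C (2.91) and IGFBP3 (2.77). Lipoprotein lipase, LPL, was higher (4.29) and FABP5 lower (-4.83).

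Stellate-like cells came mainly from clusters 1 and 6 in library 1, 21 in library 2, 20 in library 3 and 12 in library 4. Endothelial-like cells numbered 135, 104, 45 and 60, and cluster 5, led by CCL21, MMRN1 and LYVE1, supplied 91, 35, 15 and 54 of them.

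Immune-like cells were higher than all other cells for genes of antigen presentation and inflammation. CD74 was higher by a median log2 ratio of 8.43 (6.46 to 9.52), and CXCL8, a neutrophil-attracting chemokine, by 8.36 (5.02 to 9.45). The other cells include unnamed ones, among them 389 cells of library 4 in a cluster with neutrophil markers. CXCL8 stood at 4.29, 0.756, 0.136 and 62.0 CPM in the other cells of libraries 1 to 4. The part of the unnamed cells in this was not measured. The immunoproteasome subunits PSMB9 (5.12) and PSMB8 (4.94), the peptide transporter TAP1 (3.93), the NF-kB inhibitor NFKBIA (4.38), the chemokine CXCL10 (4.37) and TGFB1 (4.13) were higher. CD74 reached 7369, 9032, 4547 and 6055 CPM in immune-like cells of libraries 1 to 4.

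Of 218 list genes measured, 20 were higher, 53 lower and 145 not called. The median of all genes was 0.096, and relative to it 20 were higher and 61 lower. Antigen presentation genes were higher in 5 of 8 and chemokine and inflammatory genes in 4 of 9. Of 16 dissociation and immediate early genes, 4 were higher, with ATF3 at 2.46, DUSP1 at 2.36, ZFP36 at 2.11 and FOSB at 1.85. Hormone processing and secretion genes were lower in 11 of 17, among them PCSK1 (-6.02), SCGN (-5.63) and SLC2A2 (-4.94). Matrix genes were lower in 10 of 21 and higher in 2, TGFB1 and VIM (2.10). NKX2-2 was lower (-4.45). Vascular genes were lower in 4 of 16, with MMRN1 at -4.85, and LYVE1, which some macrophages carry, was higher (2.42). Of 14 proliferation genes, 0 were called.

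The neutrophil-like cluster 7 held 34, 3, 21 and 408 immune-like cells of libraries 1 to 4, and the macrophage/myeloid-like cluster 11 held 117, 14, 62 and 195, so the class differed in make-up between libraries. The immune-like cells numbered 265, 34, 98 and 813, and without library 2, which had 34, the higher count was 33. With a pseudocount of 10 CPM, the lower count was 25.

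**Figure D2:**
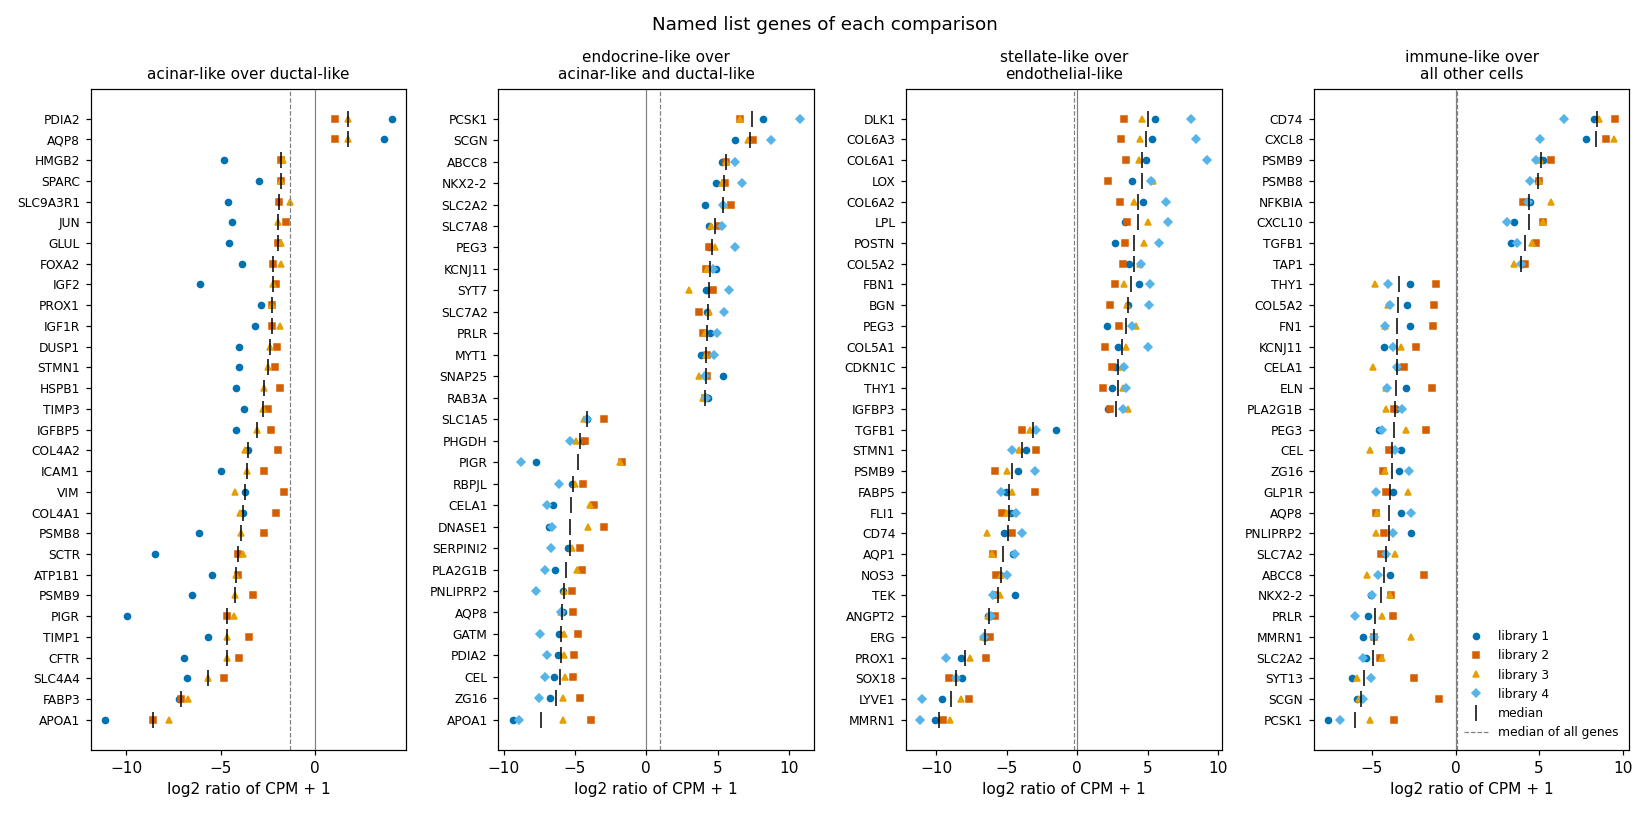
Log2 ratio of CPM + 1 between classes (horizontal axis) for named list genes of each comparison, with a symbol per library, a bar at the median and a dashed line at the median of all genes. In the first panel that line lies at -1.32, and PDIA2 and AQP8 are the only named genes above 0.

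Free RNA was described from barcodes with 10 to 100 UMIs. The 12 acinar enzyme genes took 15.0%, 7.33%, 7.37% and 1.36% of their UMIs in libraries 1 to 4, against 31.5%, 14.7%, 17.2% and 28.0% of UMIs in acinar-like cells. From the enzyme share of immune-like and endothelial-like cells, the share of background in these cells was estimated at 3.15%, 16.7%, 4.61% and 11.3%. For library 4 it was 16.99% from barcodes with 5 to 50 UMIs. LOC108634769 took 70.4% of the UMIs of barcodes with 10 to 100 UMIs in that library. This lowers the enzyme share of free RNA there and so raises the estimate, which was not recomputed without this transcript. The estimates depended on the class: in library 2 the enzyme share was 1.35% in endothelial-like, 0.663% in immune-like and 0.210% in stellate-like cells. The transcript LOC108634769 cannot decide on the higher estimates. It took 70.4% of cell-free UMIs in library 4 and 10.7% in library 2, but 1.84% and 0.395% of UMIs in called cells. Background of 11.3% and 16.7% would bring more of it than that, if it is free RNA that enters all cells alike. Its source stays open, however, and its share in the immune-like and endothelial-like cells behind the estimates was not measured. In library 4 it was the leading gene of both classes. INS, the insulin gene, took 1.97%, 1.79%, 3.73% and 3.23% of cell-free UMIs.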

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

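All tests of explanations in this part were chosen after the results were seen. A transcript outside the compared gene lists, LOC108634769, took 70.4% of the UMIs in barcodes with 10 to 100 UMIs of library 4, and 15.6%, 10.7% and 23.8% in libraries 1, 2 and 3. In barcodes with 5 to 50 UMIs it took 16.99%, 3.07%, 5.85% and 20.8%, so the share depended on the range chosen. It stood out because these barcodes enter no comparison between cells. In called cells it took 0.293%, 0.395%, 0.622% and 1.84%. In library 4, 59906 barcodes with over 100 UMIs carried this gene in the majority of their UMIs, with a median of 147 UMIs and 25 genes, and 0 of them was a called cell.

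Free RNA from cells like the called ones is argued against as the source: in library 4 the share of LOC108634769 in cell-free barcodes was 38.2 times that in called cells, while 95% of 267 other abundant genes lay between 0.158 and 1.76 times. With 5 to 50 UMIs it was 11.3 times, above the range that held 95% of 124 other genes (up to 6.50) but below the highest of them (82.8). Red blood cells could be a source and stay open. Their matched markers (ALAS2, AHSP, SLC4A1 and HBM) came to 1 of 2197270 other UMIs in those barcodes, 0.46 per 1000000 with an upper limit of 2.54, but the main globin markers on the fixed list were not used here, and the protocol included red cell lysis. No biological explanation was tested, since the libraries have no age.

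With a minimum of 1000 UMIs, a cluster of 76 barcodes appeared with KIT, CPA3 and HDC, markers of mast cells, among its 10 leading genes, with 45, 17, 8 and 6 barcodes in libraries 1 to 4 and a median of 1290.5 UMIs; these barcodes fall below the thresholds used for the comparisons.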

How the results depend on the processing

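The removal of the top 5% of doublet scores, the centring on all genes, the leaving out of LOC108634769, its share at 5 to 50 UMIs and the enzyme share per cell were chosen after seeing the data. No named gene changed sign under any alternative run, but the balance of calls turned after centring in all comparisons except the immune-like one. With at least 1000 UMIs, cells called were 4553, 9786 and 6310 in libraries 1, 2 and 4, and median shares became 13.7% (acinar-like), 18.7% (endocrine-like), 45.0% (stellate-like) and 8.37% (immune-like), because shallower barcodes entered. With at least 200 genes the acinar-like median was 19.8%. The ductal-like median was 2.59% with no doublets removed and 2.68% with the top 5% of scores removed, where the stellate-like median was 38.4%. Clustering each library on its own gave an endocrine-like median of 23.8%. Except where it follows from the alternative itself, the cause was not tested.

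For acinar-like against ductal-like cells, the higher count of 7 became 12 with at least 1000 UMIs, 17 with no doublets removed, 17 with the top 5% removed, 11 after subtracting free RNA, 15 with averages of per-cell proportions and 39 after centring. The lower count of 48 became 12 after centring. For endocrine-like cells, 35 higher and 27 lower became 27 and 36, and for stellate-like cells 18 and 22 became 21 and 20. Leaving out a library gave 8 to 17 higher calls for acinar-like cells and 20 to 33 for immune-like cells, whose lower count was 25 with a pseudocount of 10 CPM. Counts for the endocrine-like and stellate-like comparisons stayed within 1.5 times under the alternatives run. Of the 30 named genes of the acinar-like comparison, 16 lost their call after centring and 9 with at least 1000 UMIs. Of the immune-like ones, 6 lost it with 10 CPM, 5 with each library clustered alone and 3 with no doublets removed, and no other alternative took it from more than 2 genes of a comparison. Clustering alone gave 30.3% endocrine-like cells in library 4, whose share was 21.3%. Enzyme shares of free RNA were 13.0%, 6.84%, 7.57% and 0.903% in barcodes with 5 to 50 UMIs. Background shares, from immune-like and endothelial-like cells only, were then 3.64%, 17.8%, 4.48% and 16.99%. These background shares depended on the class used, and in library 4 also on LOC108634769, which lowers the enzyme share of free RNA. In library 2 enzymes took 1.35% of endothelial-like, 0.663% of immune-like and 0.210% of stellate-like UMIs, and in library 4 0.518%, 0.127% and 0.0613%. Stellate-like cells would thus give lower background shares there, but a higher one in library 1, where their enzyme share was 0.657%.

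Between the ages, no paired analysis was possible because no label ties a library to an animal or an age. Class ratios were taken within each library, and a paired test of them was not run. The comparison of ages and its alternatives (DESeq2, no filter on low counts, a replicate block, replicates left out) were not run, for want of such labels, and the 10% mitochondrial limit was not run for lack of mitochondrial genes here. Depth limits the ductal-like values of library 4, with 11 cells, and the immune-like values of library 2, with 34.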

Other observations

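All tests in this part were chosen after the values were seen. Acinar-like cells of the 4 libraries differed in which digestive genes they used, with no age assigned to any library. PNLIP stood at 13026, 0.229, 1.48 and 10908 CPM in libraries 1 to 4, CELA1 at 50044, 886, 1302 and 37276, DNASE1 at 4311, 83.1, 108 and 1606, and PLA2G1B, a secreted phospholipase, at 18264, 518, 939 and 11942. PNLIPRP2 went the other way, at 245, 2463, 6185 and 770 CPM. CYM, the milk-clotting protease chymosin, had 0 counts in library 1 (at most 0.912 CPM), 363 CPM in library 2, 526 in library 3 and 3.67 in library 4. CEL (10284, 9079, 16824 and 17004 CPM) and PRSS2 (42893, 50656, 41549 and 35101 CPM) differed less.

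Over 10038 genes, the acinar-like profiles correlated at 0.908 between libraries 1 and 4 and 0.935 between 2 and 3, and between 0.859 and 0.886 for the other pairs; genes are not independent replicates. Genes that differed at least 4-fold numbered 170 and 140 for those pairs and 1009 to 1800 for the others. In stellate-like cells the pairs 1 and 4 (0.942) and 2 and 3 (0.941) were again closest, as they were in endothelial-like cells (0.889 and 0.914). In endocrine-like cells they were closest by correlation (0.949 and 0.944), but 2 and 3 differed at least 4-fold in 168 genes against 140 for 1 and 3. In immune-like cells the pair 1 and 4 was closest (0.887), but 2 and 3 (0.831) was no closer than 1 and 3 (0.831) and differed at least 4-fold in 424 genes against 264. That class differed in make-up: neutrophil-like cells numbered 34, 3, 21 and 408 in libraries 1 to 4, and T/NK-like cells 66, 2, 1 and 137. In stellate-like cells, IGF2, a fetal growth factor, stood at 1075, 5416, 2449 and 698 CPM in libraries 1 to 4. In the PPY-led endocrine cluster, PPY took 549310, 348700, 366040 and 400480 CPM and GAST, the gastrin gene, 591, 3317, 2462 and 191 CPM.

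A pair of neighbouring genes on chromosome 18, LOC102174148 and LOC102176156, alternated between libraries in acinar-like cells. LOC102174148 stood at 160050, 51.0, 256 and 96376 CPM in libraries 1 to 4, and LOC102176156 at 364, 280590, 155810 and 45952. A fixed split of the same reads between the 2 genes cannot give this pattern, since the log2 ratio of their counts ranged over 21.2 between libraries. That range restates the alternation and is no separate test. It cannot exclude reads placed on the wrong gene where animals differ in sequence, and how alike the 2 genes are was not measured. A variant carried by an animal may contribute and stays open. In library 4, 9.86% of 71 acinar-like cells (7 cells, 95% interval 4.06% to 19.3%) preferred the other copy, against 0% in the other libraries. In any library 0 cells lay between 10% and 90%, so most of the 45952 CPM of LOC102176156 in library 4 came from those 7 cells. Clusters 23 and 27, made mainly of cells of libraries 2 and 3, held 5 and 1 of the 71. In endocrine-like cells of library 4, LOC102176156 stood at 6.37 CPM and LOC102174148 at 502. Where the 7 cells came from was not tested, so they cannot decide on a variant. Age stays open as well, untested, since no library has one.

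Ductal-like cells of libraries 2 and 3 held acinar enzyme RNA, at 32.9 and 24.2 times the share of stellate-like cells of the same library. Stellate-like cells had the lowest enzyme share of the classes compared, and endothelial-like cells held 1.35% and 0.543%. Free acinar RNA is argued against as the source of these class totals, most of which the 50 and 45 cells with an enzyme share of at least 5% carried. Those cells were picked by this share, so their own excess is no separate test. Free acinar RNA stays open for the other ductal-like cells, at 0.516% and 0.464%. Their share was 2.45 and 2.09 times that of stellate-like cells but below that of endothelial-like cells. Doublets of acinar and ductal cells are consistent with the counts: the enzyme-rich cells had 3.36 and 3.07 times the median UMIs of the others. Acinar-like cells were themselves deep (medians of 19440 and 17620 UMIs) but held fewer genes (medians of 2388 and 2530) than the enzyme-rich cells (3596 and 3343), which speaks against acinar cells placed in the ductal-like class, although no test of that was set. No biological explanation was tested.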
